A study of Drosophila melanogaster with 8 samples.

How the data were processed

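Total RNA was sequenced from testes of 5-day-old Drosophila melanogaster males in 4 groups of 2 libraries: the control strain w1118, a Tailor mutant, a Dis3L2 mutant and a double mutant. Tailor is a terminal uridylyltransferase and Dis3L2 a 3'-5' exonuclease. Per the labels' protocols, the 2 libraries of a group came from independent dissections, RNA was extracted with Trizol, 650 ng entered a TruSeq total RNA preparation amplified for 8 cycles in place of the recommended 15, and paired-end reads of 50 nt came from 2 flow cells of a HiSeq2500. Which library ran on which flow cell, the alleles and the parent strains of the mutants are not given in the sources used here.

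Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and aligned to dm6 with HISAT2. The deposited table holds a raw read count per feature and library, made by the authors. The counting tool, its annotation, its strand setting and its handling of reads with several positions are not given in the sources used here. Values of antisense genes, of repeated genes such as histones, ribosomal RNA and the 7SL copies, of close paralogs and of single transposon insertions are uncertain for that reason.

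The table held 22887 features: 17471 genes and 5416 transposon insertions, of which 2909 features had no count in any library. By symbol 13553 genes were matched to the Ensembl annotation of BDGP6, whose coordinates are those of dm6, and 3765 more by an older symbol, which left 153 unmatched; 5400 transposon insertions were matched. Positions are 1-based. The gene printed as Dis3l2 stands in the table as CG16940. The rule for named genes carried a wrong number for Tailor, and the row labelled Tailor was used.

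Total counts per library ranged from 9781275 to 30059737. Counts were analysed in R 4.3.3 with edgeR 4.0.16: trimmed mean of M values scaling, the filterByExpr filter with a minimum count of 10, a quasi-likelihood fit of all 8 libraries with group as the only term, and Benjamini-Hochberg adjustment over the 14246 features tested, 757 of them transposon insertions. A gene was called at an adjusted p of 0.05 or less. The 7 comparisons were each mutant against w1118, the double mutant against each single mutant, the single mutants against each other, and the interaction, which is the departure of the double mutant from the sum of the single mutants' log2 changes. Errors of fold changes are the absolute log2 fold change divided by the square root of the fit's F statistic. Where a group has few counts they may lie below the counting error. Errors of levels are SDs of 2 libraries, and each group has n = 2. CPM, read counts brought to a common library size, were computed with edgeR from the scaled library sizes.

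Where every count of a group was 0, a fold is given as a lower bound with 3 counts put over that group. Where the lower group had 1 to 3 counts, the ratio of scaled counts is given with an exact 95% conditional binomial interval. Both cover counting error only, since the reads carry no molecular identifiers.

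Gene lists were fixed before the data were examined: cytoplasmic and nuclear RNA decay, terminal nucleotidyltransferases, early germline, meiotic arrest, spermiogenesis, cup and comet genes, testis proteasome subunits, Y-linked fertility genes, somatic cyst and hub cells, accessory gland and ejaculatory duct, fat body, muscle sheath, blood cells, antimicrobial peptides, heat shock and Turandot genes, glutathione S-transferases and P450s, replication-dependent histones, ribosomal proteins, snRNAs, snoRNAs and scaRNAs, snoRNA hosts, RNA polymerase III small RNAs, tRNAs, ribosomal RNA, long noncoding CR genes, mitochondrial genes and microRNAs. The 37 mitochondrial features were 0 in all libraries and the microRNA pattern matched no feature, so 25 of the 27 lists were tested. Tailor and Dis3l2 were kept out of the lists; piwi stands in both the early germline and the cyst list, and Cyp6a21 in both the fat body and the P450 list. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, again with an estimated correlation, and with fry. Counts of members past the test are given over all genes and adjusted over the list alone.

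The comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the targeted genes, the 8 largest rises and 8 largest falls of each mutant against w1118 and the 4 of each in the other comparisons, among called genes with a mean of at least 5 CPM in the higher group and no overlap of the libraries compared, and up to 3 members of each list with the lowest p. Not every gene it names is printed. Alternatives fixed then were 2 other scalings in edgeR (relative log expression and upper quartile), DESeq2 1.42.0, no filter and a stricter filter, a fit of only the groups compared, a replicate block, small RNAs left out, a 2-fold minimum, and leaving out each library. An accessory gland covariate, the joint removal of 2 libraries, overlaps with a different w1118 library for each mutant and a list of midgut enzymes were added after the data were seen. That list leaves out digestive genes already noticed in the results, among them alphaTry, betaTry, CG12374, CG6295 and Bace. Upper quartile and relative log expression scaling moved the median of all genes by -0.02 to 0.04 and changed the sign of 0 of the medians behind the 47 list calls of the 7 comparisons; other list medians were not counted.

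The procedure was tested on simulated data with 14061 features, 100 of them seeded with each size of change per comparison. Changes were seeded only in features above a minimum mean count, so recovery at low counts was not measured. It recovered 26% of 2-fold and 88% of 4-fold changes in the Tailor comparison, 35% and 88% in the Dis3L2 comparison and 19% and 87% in the double mutant comparison, with 9, 10 and 10 false calls. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.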

Results

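The series holds 8 testis libraries, 2 from each of w1118, the Tailor mutant, the Dis3L2 mutant and the double mutant. Total counts were 19801288 and 21809441 in w1118, 25120105 and 24866166 in the Tailor mutant, 16904111 and 20125955 in the Dis3L2 mutant and 30059737 and 9781275 in the double mutant. Log-scale correlation of the 2 libraries of a group was 0.986 in w1118, 0.948 in the Tailor mutant, 0.979 in the Dis3L2 mutant and 0.980 in the double mutant. The Tailor mutant libraries did not lie closest to each other. Replicate 1 correlated better with double mutant replicates 1 and 2 (0.9618 and 0.9513) and w1118 replicate 1 (0.9535). Replicate 2 correlated better with w1118 replicates 1 and 2 (0.9576 and 0.9614). Ribosomal RNA features took 7.77% and 2.42% of counts in w1118, 17.6% and 16.6% in the Tailor mutant, 24.6% and 1.43% in the Dis3L2 mutant and 4.65% and 10.3% in the double mutant. Genes of the accessory gland, which makes seminal fluid proteins and adjoins the testis, took 2.57% and 2.57%, 5.72% and 1.80%, 0.655% and 1.19%, and 2.60% and 1.93% in the same order.

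The targeted genes were low where the labels place the mutations, and neither was absent. Tailor (FBgn0037470, 3R:7083225-7086083, minus strand) had 84.79 ± 3.13 CPM in w1118, 19.72 ± 1.04 in the Tailor mutant, 96.16 ± 0.84 in the Dis3L2 mutant and 21.92 ± 1.18 in the double mutant (SD, n = 2). It fell in the Tailor mutant (log2 fold change -2.10 ± 0.12, adjusted p = 0.000668) and in the double mutant (-1.95 ± 0.12, adjusted p = 0.000419). Dis3l2 (FBgn0035111, 3L:212709-216479, plus strand) had 115.79 ± 1.09 CPM in w1118, 91.73 ± 3.01 in the Tailor mutant, 10.28 ± 0.41 in the Dis3L2 mutant and 30.72 ± 0.04 in the double mutant. Its level was 8.9% of w1118 in the Dis3L2 mutant (-3.49 ± 0.12, adjusted p = 8.8e-05) and 26.5% in the double mutant (-1.91 ± 0.11, adjusted p = 0.000304). The double mutant thus kept more Dis3l2 reads than the Dis3L2 mutant (1.58 ± 0.11, adjusted p = 0.000753). Reads in a mutated gene do not say whether a working protein is made.

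**Figure D1:**
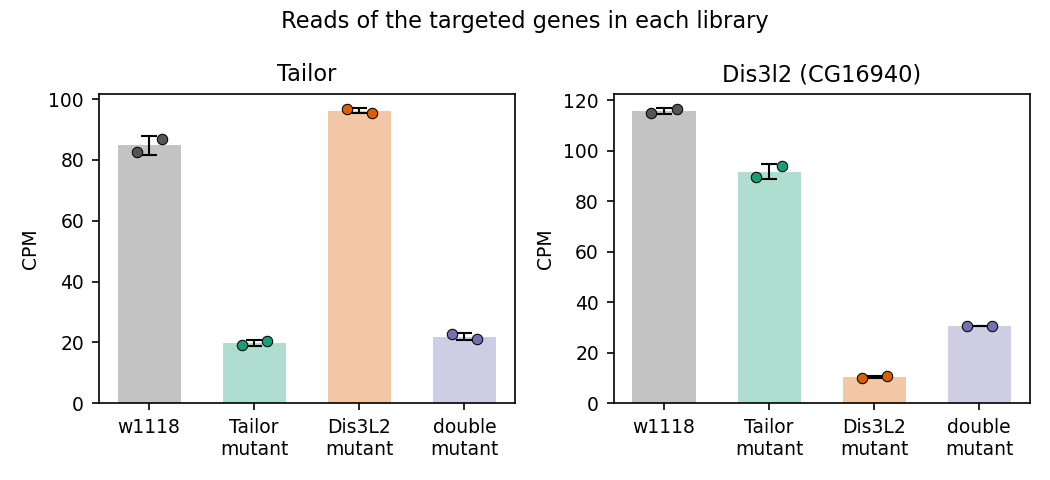
CPM of Tailor (left) and Dis3l2, CG16940 (right), in the 4 groups; points are libraries, bars group means and error bars SDs (n = 2). Tailor is low in the Tailor and double mutants, and Dis3l2 lies at 10.28 CPM in the Dis3L2 mutant and at 30.72 CPM in the double mutant.

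**Figure D2:**
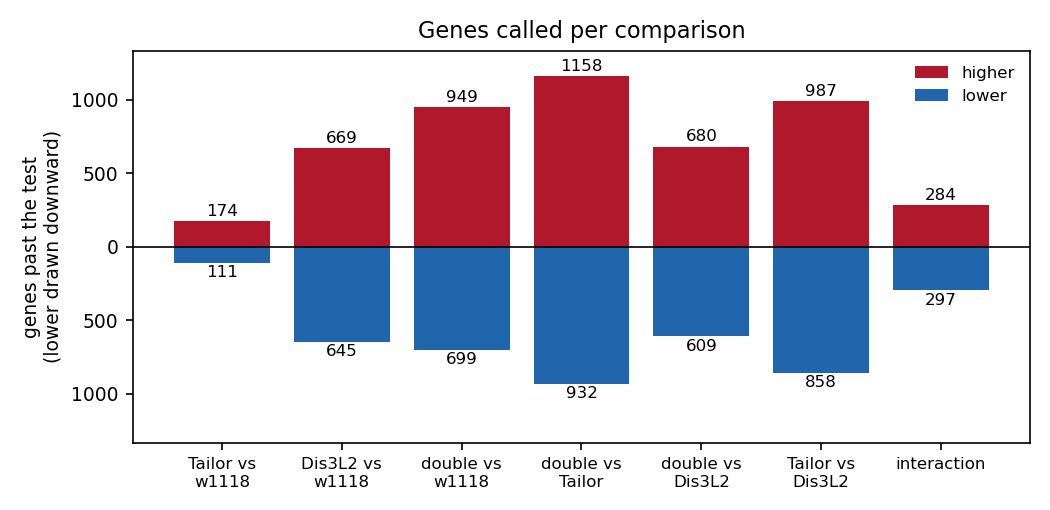
Number of genes past the test in each of the 7 comparisons, higher drawn upward and lower downward. Counts against w1118 run from 285 genes in the Tailor mutant to 1648 in the double mutant.

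Of 162 values of named genes, 96 and 91 kept their side of the test without w1118 replicates 1 and 2, 160 and 159 without Tailor mutant replicates 1 and 2, 118 and 110 without Dis3L2 mutant replicates 1 and 2, and 107 and 103 without double mutant replicates 1 and 2. None changed direction.

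The comparison of the Tailor mutant with w1118 asks which testis RNAs depend on the uridylyltransferase. A small set of genes went from nearly silent to well expressed, among them the Rab-family GTPase RabX2 and the uncharacterised CG45072, and others did the reverse, among them CG9825. Lists of germline, meiotic and sperm genes had no member past the test. In all, 174 genes rose and 111 fell, 285 together, of which 249 changed at least 2-fold, and 2099 genes had an unadjusted p under 0.05. Among 24 transposon insertions called, 18 rose and 6 fell. The total was 48 without w1118 replicate 1, 45 without w1118 replicate 2, 1113 without Tailor mutant replicate 2, 142 and 138 without Dis3L2 mutant replicates 1 and 2, and 116 without either double mutant library. It was 502 with DESeq2 and 128 without both w1118 replicate 2 and Tailor mutant replicate 1. A fit of the 4 compared libraries alone, which takes no spread from the other groups, gave 5.

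CG45072 (FBgn0266442, 3R:30122023-30123263, minus strand) rose by a log2 fold change of 6.65 ± 0.34 (adjusted p = 0.000668), from 5 counts over both w1118 libraries to 519. RabX2 (FBgn0030200, X:10417429-10418219, plus strand) rose by 6.08 ± 0.48 (adjusted p = 0.00201), CG9500 by 5.88 ± 0.40 (adjusted p = 0.00109) and CG43441 by 5.22 ± 0.28 (adjusted p = 0.000668). The long noncoding CR44537 rose 254-fold (95% interval 70.1 to 2110), from 2 counts to 501, and CR43839 (FBgn0264391, 2L:19470844-19471627, minus strand) 116-fold (31.7 to 962). On the other side, CG9825 (FBgn0034783, 2R:22837361-22839291, plus strand) fell with a log2 fold change of -6.69 ± 0.35 (adjusted p = 0.000668). The carboxypeptidase gene CG12374 fell by 7.86 ± 1.30 (adjusted p = 0.0315), a call that ended without Tailor mutant replicate 1 (0.0850), Dis3L2 mutant replicates 1 and 2 (0.0762 and 0.0816) or double mutant replicates 1 and 2 (0.0780 and 0.0825). The neighbouring noncoding genes CR43949 (3L:16020409-16021506, minus strand) and CR43950 (3L:16017165-16018317, minus strand) had no count in the Tailor mutant, a fall of at least 150-fold and at least 107-fold. The call of CR43949 ended without w1118 replicates 1 and 2 (adjusted p = 0.0797 and 0.114), and that of CR44537 without w1118 replicate 2 (0.0552). CG12374 stood at 14.5 and 163 CPM in the 2 w1118 libraries, where 31 other midgut enzyme genes summed to 72.6 and 346.8 CPM.

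Detoxification genes, the glutathione S-transferases and P450s, had the most calls of any protein-coding list in the Tailor mutant, and were the largest such list. Of 108 tested, 5 rose and 1 fell, or 11 and 3 adjusted over the list alone. Cyp4p1 rose by 2.18 ± 0.15 (adjusted p = 0.00121), GstE8 by 1.94 ± 0.21 (adjusted p = 0.00606) and Cyp6d5 by 1.75 ± 0.18 (adjusted p = 0.00606). The list median was 0.31 (camera adjusted p = 0.00281, adjusted p = 0.979 with an estimated correlation), and the call ended without Tailor mutant replicate 2 (adjusted p = 0.715).

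Lists of tissues that adjoin the testis leaned upward in the Tailor mutant with few members called. In the muscle sheath list the myosin light chain Mlc2 was the only member of 22 to rise over all genes (0.82 ± 0.14, adjusted p = 0.034), with 3 adjusted over the list alone and a median of 0.57 (camera adjusted p = 0.000146, adjusted p = 0.936 with an estimated correlation). In the fat body list 1 of 15 rose, the lipid transfer protein Apoltp (1.03 ± 0.15, adjusted p = 0.0208), also 1 over the list alone, with a median of 0.71 (camera adjusted p = 0.0233, adjusted p = 0.936 with an estimated correlation). The muscle call ended without Tailor mutant replicate 2 (adjusted p = 0.110), and the fat body call without w1118 replicate 2 (0.0584) or Tailor mutant replicate 1 (0.704), or without both (0.965). Accessory gland genes had a median of 0.82 with 0 of 25 called (camera adjusted p = 0.0754), and their share of counts was 5.72% and 1.80% in the 2 Tailor mutant libraries against 2.57% in each w1118 library.

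Camera also called 4 lists in the Tailor mutant whose single members did not pass over all genes. Antimicrobial peptides, effectors of innate immunity, had 0 of 18 past over all genes and 3 higher over the list alone, with a median of 0.94, or 0.90 with members at 0 put at their bound (adjusted p = 0.00685, adjusted p = 0.936 with an estimated correlation). Heat shock and Turandot stress genes had 0 of 20 on either count and a median of 0.69 (0.0170, adjusted p = 0.979 with an estimated correlation). Replication-dependent histones had 0 of 9 over all genes and 2 higher over the list alone, with a median of 0.57 (0.0455, adjusted p = 0.936 with an estimated correlation). Ribosomal RNA features had 0 of 14 past the test and a median of 1.56 (0.0129, adjusted p = 0.979 with an estimated correlation), beside shares of 17.6% and 16.6% of counts against 7.77% and 2.42% in w1118. Without Tailor mutant replicate 1 the antimicrobial (0.232), heat shock (0.645), histone (0.312) and ribosomal RNA (0.109) calls ended; without Tailor mutant replicate 2 the histone (0.110) and ribosomal RNA (0.0943) calls did, without w1118 replicate 2 the heat shock (0.177) and ribosomal RNA (0.175) calls, and without double mutant replicate 1 the histone call (0.0524). Without both w1118 replicate 2 and Tailor mutant replicate 1 the antimicrobial call ended (0.285), and the heat shock median was 0.14 with camera pointing down (0.731).

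Among ribosomal protein genes in the Tailor mutant 1 of 93 rose on either count, RpS28a (1.41 ± 0.22, adjusted p = 0.0268), and the median was 0.14 (camera adjusted p = 0.0591). Long noncoding CR genes had 59 of 1609 higher and 31 lower, or 108 and 58 over the list alone, with a median of 0.07. CR44777 rose by 5.07 ± 0.32 and CR46043 fell by 4.33 ± 0.25. No member passed over all genes in RNA decay (median -0.14), terminal nucleotidyltransferases (0.04), early germline (-0.10), meiotic arrest (-0.08), spermiogenesis (0.05), cup and comet genes (-0.13), testis proteasome (0.05), Y-linked genes (-0.11), cyst and hub cells (-0.17), blood cells (-0.08), snRNAs (-0.19), snoRNAs (-0.13), snoRNA hosts (0.05), RNA polymerase III small RNAs (-0.08) or tRNAs (-0.40). Over the list alone, 1 RNA decay, 1 early germline and 2 meiotic arrest genes were lower. Camera pointed down for terminal nucleotidyltransferases, spermiogenesis and the proteasome although their medians and means lay above 0.

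The Dis3L2 mutant against w1118 asks which testis RNAs depend on the exonuclease. Several antimicrobial peptide genes rose, as did the blood cell genes Pxn, a peroxidasin, and crq, a phagocytic receptor. Ribosomal protein genes leaned lower (adjusted p = 0.908 with an estimated correlation). The lipase gene CG6295 and the trypsin gene betaTry fell, calls that ended without w1118 replicate 2; of 31 other midgut enzyme genes 2 fell, and their median was 0.13. RabX2, CG45072 and CR43839, which rose in the Tailor mutant, rose here too. In all, 669 genes rose and 645 fell, 1314 together, of which 915 changed at least 2-fold, and 3501 had an unadjusted p under 0.05. Which direction held more genes depended on the setting, with 386 higher and 529 lower at a 2-fold minimum. Of 86 transposon insertions called, 38 rose and 48 fell. The total was 276 and 306 without w1118 replicates 1 and 2, 2367 and 2513 without Tailor mutant replicates 1 and 2, and 339 and 352 without Dis3L2 mutant replicates 1 and 2. It was 2531 in a fit of the 4 compared libraries alone and 82 with accessory gland level as a covariate, a fit added after the data were seen.

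CG11854 (FBgn0039299, 3R:25242020-25243262, plus strand) rose by a log2 fold change of 7.46 ± 0.37 (adjusted p = 0.000182), RabX2 by 6.97 ± 0.48 (adjusted p = 0.000578) and CG45072 by 6.52 ± 0.34 (adjusted p = 0.000232). The noncoding CR45568 (FBgn0267128, 3R:29276376-29277108, minus strand) rose at least 80.3-fold from 0 counts, CR43451 (FBgn0263405, 3R:19288357-19289296, plus strand) 586-fold (105 to 23200) and CR43839 128-fold (34.9 to 1060). CR45982 rose by 6.67 ± 0.31 (adjusted p = 0.000175). Among the falls, CG6295 (FBgn0039471, 3R:27005899-27007055, minus strand) dropped at least 312-fold, CG34324 at least 169-fold, CR43949 at least 128-fold and CG14125 at least 103-fold. CG8960 had a ratio of 0.00194 to w1118 (4.89e-05 to 0.0108). BetaTry (FBgn0010357, 2R:11346325-11347395, plus strand) fell by 8.63 ± 1.74 (adjusted p = 0.0245). In the 2 w1118 libraries CG6295 stood at 2.86 and 42.2 CPM, CG34324 at 1.16 and 23.1, CG14125 at 1.41 and 13.6 and betaTry at 10.6 and 120. The bounds of CG6295, CG34324 and CG14125 thus rest mostly on w1118 replicate 2. Without that library these 4 calls ended, and they ended also without each of the Dis3L2 and double mutant libraries in turn.

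Of 18 antimicrobial peptide genes 7 rose and 0 fell in the Dis3L2 mutant, or 9 and 2 over the list alone. The antifungal Drs rose by 4.64 ± 0.73, the attacin AttB by 4.23 ± 0.62 and the cecropin CecA1 by 1.30 ± 0.17 (adjusted p = 0.00607). The list median was 1.85 (camera adjusted p = 4.5e-05, adjusted p = 0.908 with an estimated correlation). Of 7 blood cell genes 2 rose, or 3 over the list alone: Pxn by 1.33 ± 0.16 and crq by 1.33 ± 0.20, with a median of 0.82 (camera adjusted p = 0.00792, adjusted p = 0.908 with an estimated correlation). The blood cell call ended without w1118 replicate 2 (adjusted p = 0.0547).

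Accessory gland genes leaned lower in the Dis3L2 mutant with a median of -1.62 (camera adjusted p = 2.1e-05, adjusted p = 0.908 with an estimated correlation). Of 25 tested, 1 rose and 1 fell over all genes, or 1 and 9 over the list alone. The accessory gland protein Acp98AB fell by 3.42 ± 0.59 (adjusted p = 0.0144), and EbpIII, an ejaculatory bulb protein, rose by 1.28 ± 0.20 (adjusted p = 0.0101). The share of counts from accessory gland genes was 0.655% and 1.19% against 2.57% in each w1118 library. Ribosomal protein genes had a median of -0.45 (camera adjusted p = 7.3e-09, adjusted p = 0.908 with an estimated correlation), with 1 of 93 higher and 3 lower over all genes and 0 over the list alone. RpL12 fell by 0.98 ± 0.21, RpL29 fell by 0.76 ± 0.17, and RpS28a rose by 1.01 ± 0.22.

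Germline lists changed in single members of both directions in the Dis3L2 mutant. Among 20 early germline genes, tut, an RNA-binding protein, rose by 1.23 ± 0.19 and the cyclin CycB by 0.68 ± 0.13, and Rbp9 fell by 0.80 ± 0.15 (over the list alone 2 rose and 3 fell). Among 15 meiotic arrest genes the Cdc25 phosphatase twe rose by 0.56 ± 0.12 and topi fell by 0.58 ± 0.12 (1 and 3 over the list alone). Of 30 spermiogenesis genes S-Lap5, a leucyl aminopeptidase of sperm, rose by 0.68 ± 0.13, 1 on either count. Of 14 testis proteasome subunits 3 rose and 2 fell, 4 and 3 over the list alone, with Prosalpha4T1 at 1.09 ± 0.22, Prosbeta4R2 at 1.05 ± 0.13 and Prosbeta5R2 at -0.86 ± 0.15. Of 17 cyst and hub genes Socs36E, a feedback inhibitor of JAK-STAT signalling, rose by 1.38 ± 0.21 (3 rose over the list alone). The medians were -0.10, -0.09, -0.05, 0.10 and -0.12, with mean and camera direction above 0 for spermiogenesis and cyst genes.

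Other lists gave scattered calls in the Dis3L2 mutant. Of 108 detoxification genes 5 rose and 6 fell, or 5 and 8 over the list alone (median 0.10), with Cyp311a1 at 3.52 ± 0.53, Cyp4p1 at 2.44 ± 0.16 and GstE10 at -2.38 ± 0.37. The apolipophorin gene apolpp fell by 1.58 ± 0.23 (adjusted p = 0.00781), the only call on either count among 15 fat body genes, whose median was 0.14 with a mean of -0.27 and camera pointing down. Of 9 histone genes 3 rose on either count, His2B:CG17949 by 4.28 ± 0.89, with a median of -0.03, a mean of 0.91 and camera pointing up. Of 143 snoRNA and scaRNA genes 1 fell, snoRNA:Psi28S-1192b by 5.33 ± 1.13 (adjusted p = 0.0293), 0 over the list alone, with a median of -0.17. Long noncoding CR genes had 99 higher and 153 lower, or 125 and 193 over the list alone (median -0.07); CR46260 rose by 4.36 ± 0.24. No member passed in RNA decay (median -0.07), terminal nucleotidyltransferases (0.10), cup and comet genes (0.18), Y-linked genes (0.21), muscle (-0.04), heat shock (-0.41), snRNAs (0.29), snoRNA hosts (-0.50), RNA polymerase III small RNAs (-0.21), tRNAs (-0.25, mean -0.06, camera up) or ribosomal RNA (1.65, beside shares of 24.6% and 1.43%). Over the list alone 1 snoRNA host was lower and 1 tRNA higher.

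The double mutant against w1118 asks what the joint loss does. Ribosomal protein mRNAs and snoRNAs, the guides of RNA modification, were lower as groups (adjusted p = 0.851 for each with an estimated correlation). Several genes of late sperm development were higher. Of 15 fat body genes 4 rose and 1 fell, the former including the larval serum protein Lsp1alpha and Fbp1, its receptor. RabX2 and CR43839 rose as they did in both single mutants. In all, 949 genes rose and 699 fell, 1648 together, of which 959 changed at least 2-fold, and 4325 had an unadjusted p under 0.05. The balance turned at a 2-fold minimum, where 465 rose and 494 fell. It turned also without w1118 replicate 2 and Tailor mutant replicate 1 together. Of 125 transposon insertions called, 59 rose and 66 fell. The total was 196 and 220 without w1118 replicates 1 and 2, 3393 and 3537 without Tailor mutant replicates 1 and 2, 1079 without Dis3L2 mutant replicate 2, and 385 and 350 without double mutant replicates 1 and 2. A fit of the 4 compared libraries alone gave 3786.

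**Figure D3:**
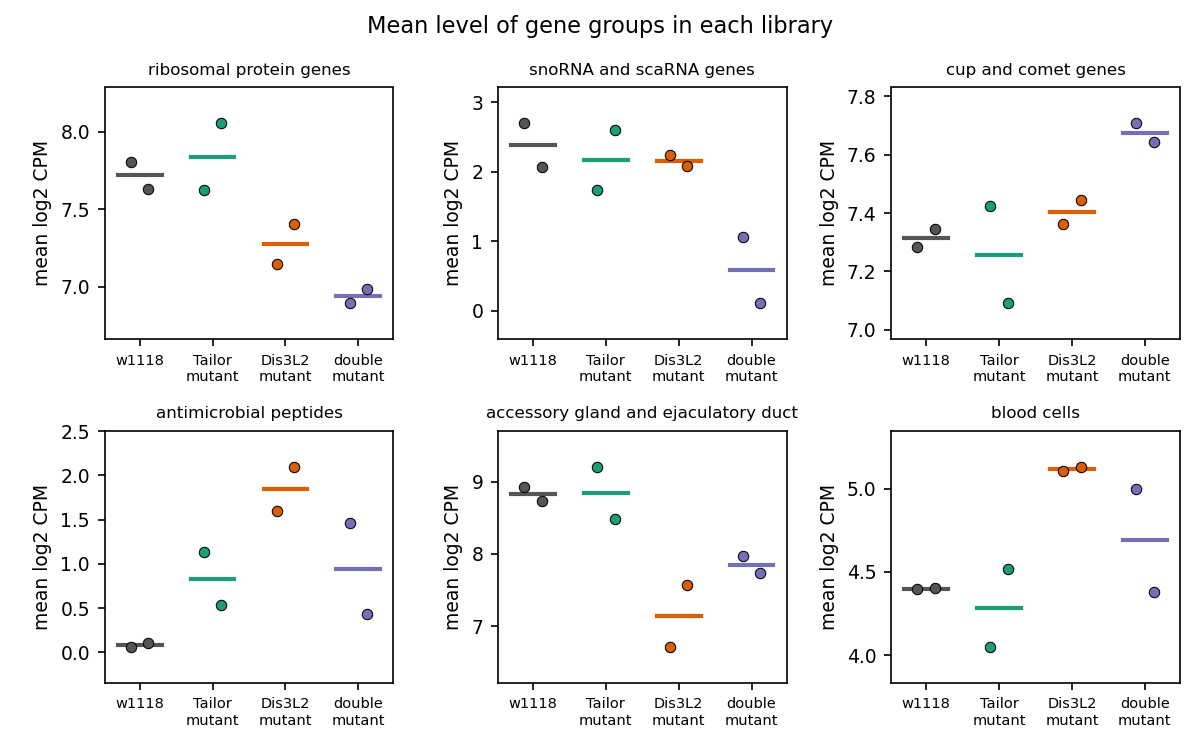
Mean log2 CPM (prior count 2) of 6 gene lists in each library; points are libraries and bars the means of 2 libraries. Ribosomal protein genes and snoRNAs are lowest in the double mutant, and the 2 Tailor mutant libraries lie apart in the accessory gland panel.

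Fbp1 (FBgn0000639, 3L:14094589-14098053, minus strand) rose 190-fold (64.5 to 922), and RabX2 rose by a log2 fold change of 7.09 ± 0.48 (adjusted p = 0.000581). The noncoding CR43263 (FBgn0262944, 2L:1216854-1217785, minus strand) rose at least 172-fold from 0 counts, CR45568 at least 96.8-fold, CR43839 379-fold (104 to 3130) and CR45742 141-fold (38.7 to 1170). CG14645 fell at least 168-fold and the methuselah-like receptor gene mthl8 (FBgn0052475, 3L:22428-26308, plus strand) at least 107-fold. CR43950 fell at least 97-fold. The aspartyl protease gene Bace had a ratio of 0.000697 to w1118 (1.76e-05 to 0.00389) and CG6295 of 0.001 (2.54e-05 to 0.00561). BetaTry fell by 8.72 ± 1.77 (adjusted p = 0.0237). In the 2 w1118 libraries CG14645 stood at 2.13 and 20.8 CPM and Bace at 5.43 and 59.8, and without w1118 replicate 2 the calls of CG14645 (adjusted p = 0.0862), Bace (0.109), CG6295 (0.110) and betaTry (0.124) ended. Without either w1118 or either double mutant library the calls of Fbp1 (adjusted p = 0.244, 0.209, 0.113 and 0.168) and CR43263 (0.112, 0.109, 0.0815 and 0.0882) ended. The 31 midgut enzyme genes, which leave out Bace, CG6295 and betaTry, summed to 40.8 and 37.4 CPM in the double mutant against 72.6 and 346.8 in w1118.

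Of 93 ribosomal protein genes 56 fell and 1 rose in the double mutant, or 78 and 2 over the list alone. RpS20 fell by 1.10 ± 0.19 (adjusted p = 0.0142), RpL29 fell by 0.98 ± 0.17 (adjusted p = 0.0145) and RpS28b fell by 0.93 ± 0.16 (adjusted p = 0.0138). The median was -0.85 (camera adjusted p = 3.3e-24, adjusted p = 0.851 with an estimated correlation). Of 143 snoRNA and scaRNA genes 46 fell and 0 rose, or 87 and 0 over the list alone. The guide scaRNA:MeU2-48 fell by 4.19 ± 0.58 (adjusted p = 0.00682) and snoRNA:Psi18S-1377b fell by 2.41 ± 0.30 (adjusted p = 0.00535). The list median was -1.70 (camera adjusted p = 4.6e-26, adjusted p = 0.851 with an estimated correlation). Of 28 snRNA genes 2 fell, or 6 over the list alone: snRNA:U2:34ABc fell by 1.65 ± 0.34 and snRNA:U2:34ABb fell by 1.64 ± 0.34, near-identical copies whose reads cannot be assigned with certainty. The snRNA median was -0.65 (camera adjusted p = 0.00448, adjusted p = 0.851 with an estimated correlation), a call that ended without w1118 replicate 1 (0.435) or double mutant replicate 2 (0.0522). RNaseP:RNA, the RNA subunit of RNase P, fell by 1.49 ± 0.30 (adjusted p = 0.0242), the only call among 8 RNA polymerase III small RNAs on either count (median -0.97).

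Of 21 cup and comet genes, which are transcribed after meiosis, 4 rose and 0 fell in the double mutant, or 8 over the list alone. Soti, needed for sperm individualization, rose by 0.80 ± 0.16, p-cup by 0.59 ± 0.14 and sunz by 0.58 ± 0.12, and the list median was 0.43 (camera adjusted p = 0.00124, adjusted p = 0.851 with an estimated correlation). Of 30 spermiogenesis genes 2 rose on either count, S-Lap5 by 1.04 ± 0.13 and the sperm chromatin gene Mst77F by 0.69 ± 0.16, with a median of 0.28 (camera adjusted p = 0.00448, adjusted p = 0.851 with an estimated correlation). Earlier stages had calls in the same direction. Of 20 early germline genes 4 rose on either count, among them CycB by 0.84 ± 0.13, the translational repressor mei-P26 by 0.79 ± 0.14 and bgcn by 0.70 ± 0.14. Of 15 meiotic arrest genes 2 rose on either count: twe rose by 0.92 ± 0.12 and the RNA-binding protein gene bol by 0.62 ± 0.13. The Y-linked dynein heavy chain kl-5 rose by 0.58 ± 0.15 (adjusted p = 0.0444), 1 of 11 over all genes and 0 over the list alone. Of 14 testis proteasome subunits 3 rose and 1 fell, 5 and 1 over the list alone, with Prosbeta4R2 at 1.04 ± 0.13, Prosalpha4T2 at 0.79 ± 0.14 and Prosbeta5R2 at -1.61 ± 0.16. Medians were -0.19 for early germline, -0.04 for meiotic arrest, -0.07 for Y-linked and 0.30 for proteasome genes; camera pointed up for all 4.

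Enzymes of RNA turnover other than the targeted genes showed few calls in the double mutant against w1118. The deadenylase gene Pop2 rose by 0.67 ± 0.10 (adjusted p = 0.00909), 1 of 25 RNA decay genes on either count, whose median was -0.17 with a mean of -0.05 and camera pointing up. The poly(A) polymerase genes Gld2 (0.61 ± 0.13, adjusted p = 0.0255) and Trf4-2 (0.51 ± 0.12, adjusted p = 0.0366) rose among 7 terminal nucleotidyltransferases, or 3 higher and 1 lower over the list alone (median 0.18). Of 108 detoxification genes 8 rose and 12 fell, or 9 and 13 over the list alone (median -0.25), with GstE8 at 2.85 ± 0.21, Cyp4p1 at 2.73 ± 0.16 and Cyp305a1 at 1.52 ± 0.13. Long noncoding CR genes had 174 higher and 102 lower, or 204 and 126 over the list alone (median 0.04), with CR44344 at 5.78 ± 0.29, CR46260 at 5.65 ± 0.24 and CR44750 at 4.06 ± 0.21.

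Of 15 fat body genes 4 rose and 1 fell in the double mutant, or 6 and 2 over the list alone: Lsp1alpha rose by 5.93 ± 1.05 (adjusted p = 0.0206), Fbp2 by 4.56 ± 1.01 (adjusted p = 0.0311), and apolpp fell by 1.57 ± 0.23 (median 0.62, camera adjusted p = 0.193). The calls of Lsp1alpha and Fbp2 ended without either w1118 or either double mutant library. The list summed to 414.9 and 361.5 CPM in w1118 and to 224.5 and 235.8 CPM in the double mutant. Its mean log2 CPM was 0.927 and 0.953 in w1118 and 2.448 and 2.573 in the double mutant. This mean was 2.476 and 0.938 in the Tailor mutant and 0.721 and 0.91 in the Dis3L2 mutant. The higher mean was thus shared with Tailor mutant replicate 1. Antimicrobial peptides had 0 of 18 past the test on either count with a median of 1.46 (camera adjusted p = 0.0167, adjusted p = 0.851 with an estimated correlation), a call that ended without double mutant replicate 1 (0.385). Pxn rose by 1.69 ± 0.16, 1 of 7 blood cell genes on either count (median 0.30), the chaperone gene DnaJ-1 by 0.75 ± 0.14, 1 of 20 heat shock genes on either count (0.33), and His2B:CG17949 by 4.24 ± 0.90, 1 of 9 histones over all genes and 2 over the list alone (0.84, camera adjusted p = 0.0739). Of 17 cyst and hub genes Socs36E rose by 1.26 ± 0.21 and rho, a protease that releases EGF ligands, fell by 2.05 ± 0.33 (2 and 2 over the list alone, median -0.07 with camera pointing up). Accessory gland genes had a median of -0.29 (camera adjusted p = 0.207) with 1 of 25 lower, Acp32CD (-0.73 ± 0.18), and 0 over the list alone. The mean of that list was -1.04. The ejaculatory bulb genes Ebp, EbpII and Sfp60F, the last of which is not on the list, summed to 353.7 and 350.5 CPM in w1118. Their sums were 1.753 and 544.5 in the Tailor mutant, 11.12 and 169 in the Dis3L2 mutant and 0.8025 and 1.974 in the double mutant. No member passed in the muscle (median 0.10), snoRNA host (-0.56), tRNA (-0.70) and ribosomal RNA lists (0.08, mean -0.29, camera down).

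The double mutant against the Tailor mutant asks what differs when Dis3L2 is mutated as well. CG43320 and the Sox transcription factor gene Sox21b rose, ribosomal protein genes and snoRNAs fell in large numbers, and 11 of 21 cup and comet genes rose. In all 1158 genes rose and 932 fell, 2090 together, 897 of them at least 2-fold, with 4726 at an unadjusted p under 0.05 and 96 transposon insertions called. The balance turned at a 2-fold minimum (326 higher and 571 lower), without Tailor mutant replicate 1 (1687 and 2082), without that library and w1118 replicate 2 (855 and 1561), and with the accessory gland covariate (535 and 643). CG43320 (FBgn0263025, 3R:27695235-27696531, plus strand) rose by 5.93 ± 0.39 (adjusted p = 0.00114), CG9825 by 5.81 ± 0.36 (adjusted p = 0.000814), Sox21b (FBgn0042630, 3L:14112405-14131324, minus strand) by 5.77 ± 0.52 (adjusted p = 0.00336) and CR44612 by 6.11 ± 0.99 (adjusted p = 0.0125, or 0.0559 and 0.0798 without double mutant replicates 1 and 2). A jockey transposon insertion (FBti0020092, 3L:11329750-11332879) had a ratio of 0.00212 (0.000437 to 0.00621), CR46108 of 0.00333 (0.000686 to 0.00977) and CR44537 of 0.00659 (0.00135 to 0.0194). The total was 792 and 767 without w1118 replicates 1 and 2, 3769 without Tailor mutant replicate 1, and 410 and 126 without double mutant replicates 1 and 2. It was 20 in a fit of the compared libraries alone and 1178 with the accessory gland covariate.

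Of 93 ribosomal protein genes 72 were lower in the double mutant than in the Tailor mutant, 83 over the list alone (median -1.01, camera adjusted p = 4.3e-33, adjusted p = 0.743 with an estimated correlation), and 38 of 143 snoRNAs were, 74 over the list alone (-1.58, 4.1e-21, adjusted p = 0.743 with an estimated correlation). Of 21 cup and comet genes 11 were higher, 12 over the list alone (0.57, 2.7e-05, adjusted p = 0.743 with an estimated correlation), and 4 of 30 spermiogenesis genes, 5 over the list alone (0.24, 0.00193, adjusted p = 0.743 with an estimated correlation). In the fit of the compared libraries alone 9 genes of any kind were higher and 11 lower. Most of the ribosomal protein and snoRNA calls thus rest on spread taken from the other groups. Detoxification genes had 5 higher and 12 lower, 5 and 13 over the list alone (-0.68, 0.000707, adjusted p = 0.743 with an estimated correlation). RNA decay genes had 6 of 25 higher and 0 lower on either count (median -0.10, mean 0.08, camera adjusted p = 0.152). Of 7 terminal nucleotidyltransferases 2 were higher and 1 lower, or 3 and 1 over the list alone (median 0.20, camera adjusted p = 0.297). Fry passed the latter list (adjusted p = 0.0397), which camera did not. The snRNAs had 2 lower on either count (-0.65, 0.0104, adjusted p = 0.777 with an estimated correlation) and muscle genes 2, or 6 over the list alone (-0.50, 0.0112, adjusted p = 0.743 with an estimated correlation). Accessory gland genes had 2 of 25 lower, 1 over the list alone (-1.07, 0.00451, adjusted p = 0.743 with an estimated correlation), with shares of 2.60% and 1.93% against 5.72% and 1.80%. Without Tailor mutant replicate 1 the accessory gland median turned to 0.20 (0.668) and the snRNA call ended (0.477). Without Tailor mutant replicate 2 the spermiogenesis (0.141), muscle (0.212) and detoxification (0.0955) calls ended, without double mutant replicate 1 the muscle call (0.297) and without double mutant replicate 2 the snRNA call (0.096).

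The double mutant against the Dis3L2 mutant asks what differs when Tailor is mutated as well; the groups differ also in Dis3l2 reads (30.72 and 10.28 CPM). The serine protease gene CG7542 and several noncoding RNAs rose, CG11854 fell, and 25 snoRNAs and 6 snRNAs fell. In all 680 genes rose and 609 fell, 1289 together, 872 of them at least 2-fold, with 3841 at an unadjusted p under 0.05 and 109 transposon insertions called. At a 2-fold minimum 436 rose and 436 fell. CG7542 (FBgn0036738, 3L:17549826-17550980, plus strand) rose 156-fold (53.1 to 759), CR46039 271-fold (92.6 to 1320) and CR43808 152-fold (51.9 to 742). The call of CR43808 ended without Dis3L2 mutant replicates 1 and 2 (adjusted p = 0.0578 and 0.0675). CG11854 fell by 8.43 ± 0.42 (adjusted p = 0.000332), and CR43451 had a ratio of 0.00191 (4.81e-05 to 0.0107). The total was 612 and 577 without w1118 replicates 1 and 2, 2785 and 2844 without Tailor mutant replicates 1 and 2, 226 and 195 without Dis3L2 mutant replicates 1 and 2, 271 and 249 without double mutant replicates 1 and 2, and 1955 without both w1118 replicate 2 and Tailor mutant replicate 1. It was 2152 in a fit of the compared libraries alone and 676 with the accessory gland covariate.

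Of 143 snoRNAs 25 were lower in the double mutant than in the Dis3L2 mutant, 66 over the list alone (median -1.55, camera adjusted p = 2.3e-22, adjusted p = 0.827 with an estimated correlation), and 6 of 28 snRNAs on either count (-1.01, 3.1e-06, adjusted p = 0.827 with an estimated correlation). Ribosomal protein genes had 0 of 93 past the test on either count with a median of -0.36 (1.9e-05, adjusted p = 0.827 with an estimated correlation). Cup and comet genes had 3 higher, 5 over the list alone (0.30, 0.0115, adjusted p = 0.827 with an estimated correlation), spermiogenesis genes 1 on either count (0.34, 0.00982, adjusted p = 0.827 with an estimated correlation) and heat shock genes 1 on either count (0.60, 0.0388, adjusted p = 0.827 with an estimated correlation). Long noncoding CR genes had 175 higher and 70 lower, 220 and 89 over the list alone (0.18, 0.00901, adjusted p = 0.827 with an estimated correlation). Accessory gland genes had 1 higher and 1 lower, 4 and 2 over the list alone (1.21, 0.0115, adjusted p = 0.827 with an estimated correlation), with shares of 2.60% and 1.93% against 0.655% and 1.19%. Without Dis3L2 mutant replicate 1 the spermiogenesis (0.0587), accessory gland (0.265), heat shock (0.0587) and CR (0.0646) calls ended, and without double mutant replicate 2 the heat shock call (0.430).

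The single mutants against each other share no w1118 library and test directly where their effects differ. Most accessory gland genes and some muscle and ribosomal protein genes were higher in the Tailor mutant, and 3 of 7 blood cell genes were higher in the Dis3L2 mutant. In all 987 genes were higher in the Tailor mutant and 858 lower, 1845 together, with 4015 at an unadjusted p under 0.05 and 80 transposon insertions called. Of these, 1101 differed at least 2-fold, 762 higher and 339 lower. CG7542 was 152-fold higher in the Tailor mutant (51.8 to 741), CR43453 238-fold (42.3 to 9430) and CR45317 at least 88.1-fold, the last with adjusted p = 0.0594 and 0.0599 without Dis3L2 mutant replicates 1 and 2. CG11854 was lower there by -7.62 ± 0.38 (adjusted p = 0.000275), Sox21b by -5.40 ± 0.52 (adjusted p = 0.0022) and CG9825 by -5.39 ± 0.36 (adjusted p = 0.000775). The total was 951 and 988 without w1118 replicates 1 and 2 and 372 and 493 without Dis3L2 mutant replicates 1 and 2. It was 418 in a fit of the compared libraries alone and 36 with the accessory gland covariate.

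Of 25 accessory gland genes 17 were higher and 1 lower in the Tailor mutant than in the Dis3L2 mutant, 18 and 1 over the list alone (median 2.29, camera adjusted p = 1.7e-07, adjusted p = 0.770 with an estimated correlation), with shares of 5.72% and 1.80% against 0.655% and 1.19%. Ribosomal protein genes had 15 higher, 57 over the list alone (0.60, 2.6e-13, adjusted p = 0.770 with an estimated correlation), muscle genes 7, or 8 over the list alone (0.60, 0.00139, adjusted p = 0.770 with an estimated correlation), and blood cell genes 3 lower on either count (-0.81, 0.0091, adjusted p = 0.770 with an estimated correlation). Heat shock genes had 2 higher, 8 higher and 1 lower over the list alone (1.29, 0.0167, adjusted p = 0.770 with an estimated correlation). Fat body genes had 3 higher on either count (1.02, or 0.84 with members at 0 put at their bound, 0.0450, adjusted p = 0.770 with an estimated correlation). Without Tailor mutant replicate 1 the fat body (0.413) and heat shock (0.282) calls ended, without Tailor mutant replicate 2 the muscle call (0.188), and without Dis3L2 mutant replicates 1 and 2 the fat body call (0.0551 and 0.0617).

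The interaction asks whether the double mutant departs from the sum of the single mutants' log2 changes. Some genes, such as CG45072, rose in each single mutant and stayed near the w1118 level in the double mutant. Others, such as CG7542 and the odorant receptor gene Or22b, were lost in the Dis3L2 mutant and present in the double mutant. In all 284 genes lay above the sum and 297 below it, 581 together, 508 of them at least 2-fold, with 3173 at an unadjusted p under 0.05 and 57 transposon insertions called. Which side held more genes depended on the setting. Under relative log expression scaling 320 lay above and 293 below, and with the accessory gland covariate 399 and 273. Without Tailor mutant replicate 1 the share below the sum grew. CG45072 had 5 counts in w1118, 519 in the Tailor mutant, 413 in the Dis3L2 mutant and 6 in the double mutant (interaction -12.75 ± 0.48, adjusted p = 0.000198). CG7542 had 953, 534, 3 and 497 (8.02 ± 0.39, adjusted p = 0.000456), CR44824 had 121, 11, 16 and 294 (7.44 ± 0.73, adjusted p = 0.00496), Or22b had 259, 182, 1 and 167 (7.39 ± 1.22, adjusted p = 0.0258) and CR44572 had 5, 115, 224 and 2 (-11.22 ± 0.73, adjusted p = 0.00121). The call of Or22b ended without each of the w1118, Dis3L2 and double mutant libraries in turn. Fitted values with a group at 1 to 3 counts depend on the fit's prior. The total was 70 and 71 without w1118 replicates 1 and 2, 1882 and 956 without Tailor mutant replicates 1 and 2, 112 and 85 without Dis3L2 mutant replicates 1 and 2, 74 and 76 without double mutant replicates 1 and 2, and 1088 with DESeq2.

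**Figure D4:**
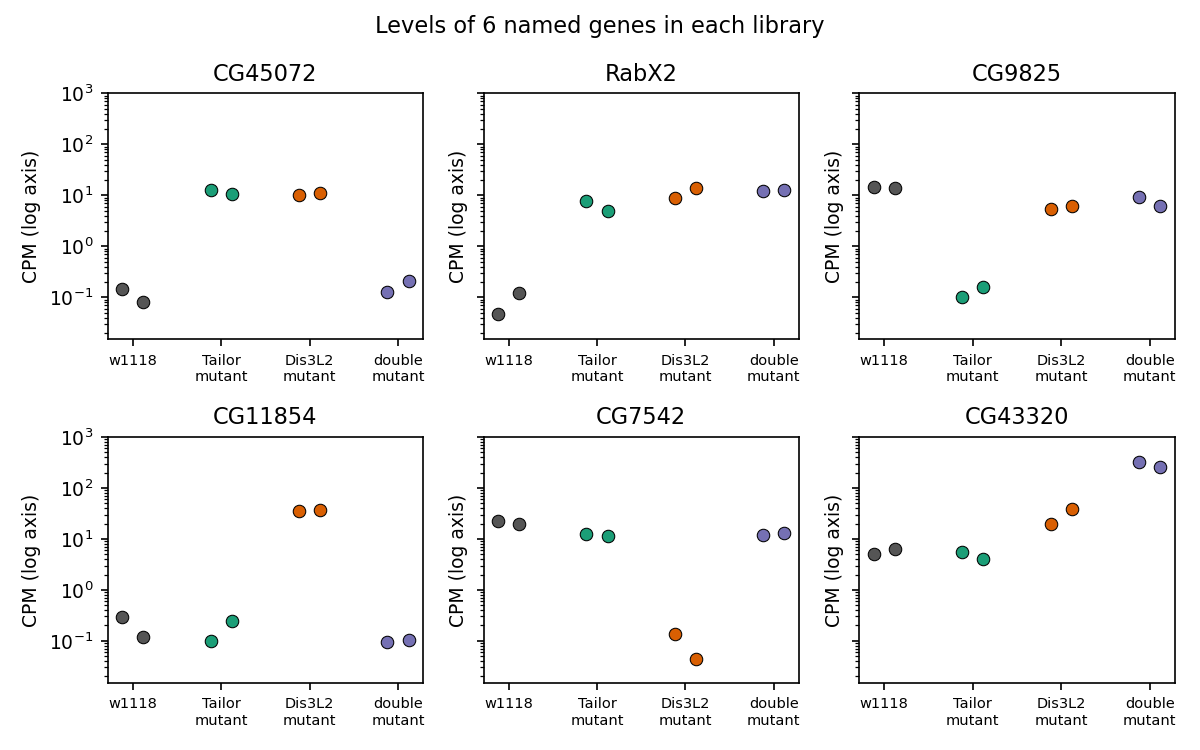
CPM on a log axis of 6 genes in each of the 8 libraries, drawn as points by group; the genes are among those the rule names. CG45072 is near 0 in w1118 and the double mutant, and CG7542 is near 0 in the Dis3L2 mutant alone.

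Of the groups, snoRNAs lay below the sum in the interaction (median -1.43, camera adjusted p = 1.4e-12, adjusted p = 0.921 with an estimated correlation) with 3 of 143 lower, 2 over the list alone, and ribosomal protein genes did (-0.50, 1.3e-06, adjusted p = 0.921 with an estimated correlation) with 1 of 93, 0 over the list alone. The snRNAs had 0 of 28 past (-0.87, 0.000756, adjusted p = 0.921 with an estimated correlation) and antimicrobial peptides 3 of 18 lower, 1 higher and 5 lower over the list alone (-1.80, 0.00279, adjusted p = 0.921 with an estimated correlation). Detoxification genes had 2 higher and 6 lower, 3 and 14 over the list alone (-0.60, 0.00105, adjusted p = 0.921 with an estimated correlation). Cup and comet genes had 1 higher, 3 over the list alone (0.39, 0.0061, adjusted p = 0.921 with an estimated correlation), and spermiogenesis genes 1 on either count (0.15, 0.0204, adjusted p = 0.921 with an estimated correlation). Ribosomal RNA had 0 of 14 past (-3.47, 0.0061, adjusted p = 0.921 with an estimated correlation), and without Dis3L2 mutant replicate 1, the library with a share of 24.6%, its median turned to 0.73 (0.877). Without Tailor mutant replicate 1 the snRNA (0.0847) and ribosomal RNA (0.0580) calls ended, without Tailor mutant replicate 2 the spermiogenesis (0.436), cup and comet (0.219) and detoxification (0.0810) calls, without Dis3L2 mutant replicate 1 the spermiogenesis call (0.115) and without double mutant replicate 1 the ribosomal RNA call (0.0816).

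The mutants shared changed genes and were compared with the same 2 w1118 libraries. The Tailor and Dis3L2 mutants shared 88 higher genes, where independent lists would share 8.17, and 42 lower genes against 5.03. The Tailor and double mutants shared 126 higher against 11.59 and 55 lower against 5.45, and the Dis3L2 and double mutants 312 higher against 44.57 and 205 lower against 31.65. In 20 simulations of unchanged groups against shared controls at most 1 gene was shared, but such groups make almost no calls, so this does not measure what the shared controls add. Covariances of log2 changes were 0.434, 0.527 and 0.646 against 0.105, 0.104 and 0.104 in the simulations, while correlations were 0.465, 0.534 and 0.52 against 0.493, 0.485 and 0.481. With 1 w1118 library per mutant, an alternative added after the results were seen, the covariance was 0.621 and 0.624 for Tailor and Dis3L2 with the same library and 0.36 and 0.393 with different ones. It was 0.659 and 0.726 against 0.399 and 0.491 for Tailor and double, and 0.761 and 0.863 against 0.529 and 0.587 for Dis3L2 and double. Shared higher genes numbered 22 and 22 with the same library and 21 and 22 with different ones, then 29 and 24 against 26 and 26, and 57 and 51 against 50 and 51, in the same order of pairs. Shared lower genes numbered 4 and 9 against 4 and 4, 11 and 16 against 11 and 11, and 27 and 39 against 21 and 25, where independent lists of different libraries would share 0.07 to 1.19 genes. Part of the excess may come from the shared controls. Called in opposite directions were 8, 4 and 34 genes. The shared counts moved with each library left out, down to 22, 4, 24, 11, 51 and 27 without a w1118 library and up to 188, 127, 346, 203, 645 and 532 without Tailor mutant replicate 2.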

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

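Tests of depth, transcript length and host genes were written down before the result they address was seen, and the tests on switched genes, organ markers and other short RNAs were chosen after it. The results here were singled out because the test of the interaction found a difference between the Dis3L2 mutant against w1118 and the double mutant against the Tailor mutant. It found 581 genes. At its ends lay CR43453 (8.17), CG7542 (8.02), CR44824 (7.44), Or22b (7.39), CG45072 (-12.75), CR44572 (-11.22), CR44537 (-9.70) and CR43451 (-9.57). The interaction of Dis3l2 (CG16940) itself was 1.91. List medians were 0.15 for spermiogenesis, 0.39 for cup and comet, -1.80 for antimicrobial peptide, -0.60 for detoxification, -0.50 for ribosomal protein, -0.87 for snRNA, -1.43 for snoRNA and -3.47 for ribosomal RNA genes (adjusted p = 0.921 for each with an estimated correlation). The last turned to 0.73 without Dis3L2 mutant replicate 1.

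If loss of the gene alone set the genes switched at least 16-fold between a single mutant and w1118, nearly all should keep their change in the double mutant; 56 of 118 kept at least 50% of the log2 change for Dis3L2 (47.5%, 95% interval 38.2 to 56.9) and 38 of 52 for Tailor (73.1%, 59 to 84.4). This biological explanation stays open for both, since the double mutant keeps more Dis3l2 reads than the Dis3L2 mutant, and since genes chosen with 1 Tailor mutant library kept the change in 73.4% of cases in the other (116 of 158) and in 70.3% in the double mutant (97.8% and 50.4% for Dis3L2). All these changes were taken against the same w1118 libraries. A gene that deviates in w1118 alone therefore counts as kept, which can raise every percentage of kept genes given here. The size of this effect was not tested. Variants carried along chromosome 3, where both genes lie, were a candidate explanation. Against uncalled genes of like expression the odds ratio of lying there was 1.49 for Tailor (0.805 to 2.76, Fisher exact p = 0.187). This cannot be told apart from no excess. For Dis3L2 it was 0.983 (0.654 to 1.47, Fisher exact p = 1), so the switched genes were not concentrated on that chromosome. The test takes both arms whole and cannot exclude variants close to the mutated gene. Different transposon insertions between the stocks stay open, with an odds ratio of 1.36 (0.661 to 2.58, Fisher exact p = 0.371; 12 of 141). Differences elsewhere in the strains' genomes were not tested, since genotypes were not analysed here.

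Libraries of a group lay apart in RNA of organs near the testis. Midgut enzyme genes were higher in w1118 replicate 2 than replicate 1 by a median log2 ratio of 1.51 (middle 50% from 0.31 to 3.24, 26 of 31 higher), a list without the genes noticed first, such as alphaTry (11.2 and 133 CPM), betaTry (10.6 and 120) and CG12374 (14.5 and 163); gut tissue in the dissection may account for it, and this stays open. Accessory gland protein genes were higher in Tailor mutant replicate 1 than replicate 2 by 1.94 (1.47 to 2.21, 18 of 20 higher), with Acp95EF the most abundant at 6240 and 1440 CPM, which fits more gland tissue in that dissection. The ejaculatory bulb genes Ebp, EbpII and Sfp60F had a median ratio of -8.72 with 0 of 3 higher. For these 3 genes this argues against a larger piece of the whole lower tract. They were chosen after the values were seen, and the bulb protein gene EbpIII was not among them. How many of these genes testis itself expresses cannot be read from these libraries, and no biological explanation was tested.

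Ribosomal protein mRNAs and snoRNAs were low in the double mutant (adjusted p = 0.851 for each with an estimated correlation), where the ejaculatory bulb genes were low too (0.8025 and 1.974 CPM against 353.7 and 350.5 in w1118) and midgut enzyme genes had a median of -2.17 (0.98 in the Tailor and 0.13 in the Dis3L2 mutant); a part played by the tissue dissected was not tested. Low depth of its replicate 2 is argued against, since without that library the medians were -0.90 (-0.93 to -0.86) and -1.37 (-1.46 to -1.28, 157 genes tested). These intervals resample genes and do not measure the spread between libraries. Short transcripts in general are argued against for ribosomal protein genes, because genes matched on length and expression had a median of 0.22 (0.11 to 0.29 over 1000 draws). Genes of late sperm development, some of which rose in the double mutant, were not kept out of the matched genes. A fall with length could be masked in part by them. Other short noncoding RNAs had a median of -0.70 (-1.01 to -0.51, 41 genes), so that low recovery of all short RNAs may account for part of the snoRNA change and stays open. Changes of snoRNAs did not follow those of their host genes, with Spearman rho -0.07 (-0.24 to 0.09, permutation p = 0.41, 130 pairs, 57 hosts). The interval and p treat the pairs as independent although many share a host. They understate the uncertainty, so dependence on the host is argued against only weakly.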

How the results depend on the processing

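All settings here were fixed before the data were examined except the accessory gland covariate, the joint removal of 2 libraries and the use of 1 w1118 library for one mutant and the other for the second, and these 3 tests were chosen after the results were seen. A library left alone in its group is assumed to vary like the other groups. Leaving out 1 library gave 45 to 1113 genes for the Tailor mutant (285), 276 to 2513 for the Dis3L2 mutant (1314), 196 to 3537 for the double mutant (1648), 126 to 3769 for double against Tailor (2090), 195 to 2844 for double against Dis3L2 (1289), 372 to 2521 for Tailor against Dis3L2 (1845) and 70 to 1882 for the interaction (581). Shared genes ranged from 22 to 188 and 4 to 127 (Tailor and Dis3L2, higher and lower), 24 to 346 and 11 to 203 (Tailor and double), and 51 to 645 and 27 to 532 (Dis3L2 and double). With a different w1118 library for each mutant, in the 2 orders, they numbered 21 and 22 higher and 4 and 4 lower, 26 and 26 higher and 11 and 11 lower, and 50 and 51 higher and 21 and 25 lower. Joint removal of w1118 replicate 2 and Tailor mutant replicate 1 gave 128, 973, 1120, 2416, 1955, 1463 and 732. Fits of only the groups compared gave 5, 2531, 3786, 20, 2152 and 418, with none possible for the interaction. The accessory gland covariate gave 414 (Tailor), 82 (Dis3L2), 1445 (double), 1178 (double against Tailor), 676 (double against Dis3L2), 36 (single mutants) and 672 (interaction). Of the 1445 genes, 758 were among the 1648. With group in the fit, the covariate's slope rests on differences between libraries of a group. Its level differed between groups too, so lost calls do not separate tissue from genotype. DESeq2 gave 502 for the Tailor mutant, 1088 for the interaction, 79 shared lower genes for Tailor and Dis3L2 and 90 for Tailor and double. At least 2-fold were 959 (double), 897 (double against Tailor) and 1101 (single mutants). A minimum fold lowers counts by construction, and the cause of the other shifts was not tested. Between the 2 Tailor mutant libraries 1786 genes lay at least 2-fold apart. The numbers were 571 in w1118, 751 in the Dis3L2 mutant and 1097 in the double mutant. The fit of all 8 libraries shares its estimate of spread across groups. Tests of the Tailor mutant therefore rest in part on the spread of groups whose libraries lay closer together. Relative log expression, upper quartile, no filter, the stricter filter and small RNAs left out kept the total of each comparison within 1.5 times; with no filter the lower genes of the Tailor mutant went from 111 to 172. Of these, shared genes were counted again only under relative log expression.

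Libraries share only a number, so the pairing is not part of the design. With a replicate block the counts were 152, 851, 991, 1127, 696, 1.1e+03 and 220. Between pairs of groups, deviations of same-numbered libraries from their group correlated at -0.30 to 0.30. These are not correlations of whole libraries. Of 8 libraries, 3 correlated best with their own number.

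Of 47 list calls by camera, 47 stayed under relative log expression and the block, 0 with fry or an estimated correlation, 36 to 46 without 1 library and 36 without the pair. The heat shock median in the Tailor mutant ranged from 0.28 to 0.80 without 1 library and was 0.14 without the pair, where camera turned (adjusted p = 0.731). The accessory gland median of double against Tailor ranged from -1.60 to 0.20, the latter without Tailor mutant replicate 1, and was 0.19 without the pair. The ribosomal RNA interaction ranged from -4.59 to 0.73, the latter without Dis3L2 mutant replicate 1. The cause was not tested. Of 162 values of named genes, 161 kept their side of the test under relative log expression, 155 with DESeq2, 141 under the block and 91 to 160 without 1 library, with 0 reversed. The rule for named genes made reversals unlikely from the start. Of simulated 2-fold changes, seeded only in features above a minimum mean count, 19% to 35% were recovered. Depth was not varied in the simulation.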

Other observations

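All observations here, and the tests on them, were chosen after the values were seen, except the comparison of snoRNAs by host gene, which was written down before. Families of transposons, mobile elements whose RNA is held down in the germline, differed between the mutants. Of 15 Burdock insertions tested 9 fell in the Dis3L2 mutant and 7 rose in the double mutant, with family sums of 44.6 CPM in w1118, 74.2 in the Tailor mutant, 7.0 in the Dis3L2 mutant and 109.7 in the double mutant. Of 9 I element insertions 7 fell in the Dis3L2 mutant (9.7, 5.2, 0.9 and 1.9 CPM in the same order), and 4 of 8 Tirant insertions did (8, 3.1, 0.7 and 3.9). Of 40 jockey insertions 15 fell in the double mutant (500.6, 532.3, 343.4 and 185.2, with 386.7 and 678 in the 2 Tailor mutant libraries), and of 14 X element insertions 8 rose there (6, 10.1, 9.7 and 27.7). Of 5 springer insertions 4 rose in both the Tailor and the double mutant (9.9, 107.5, 12.2 and 73.8), with 3.6 and 16.2 in the 2 w1118 libraries. Sums of the telomeric element HeT-A in the 4 groups were 204.4, 109, 72.7 and 149.9 CPM. Reads of repeats shared by several insertions cannot be assigned to 1 of them.

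The 3S18 family had 4 of 10 insertions higher in the Dis3L2 mutant (292.1, 294.8, 547.6 and 161.1 CPM), and copia sums per library were 76.4 and 120.6 CPM in w1118, 58.5 and 145.6 in the Tailor mutant, 281.9 and 141.8 in the Dis3L2 mutant and 43.8 and 33.7 in the double mutant. The eye pigment transporter gene white (w), which is mutated in the w1118 strain, had 123 and 154 counts in w1118, 199 and 192 in the Tailor mutant, 625 and 1173 in the Dis3L2 mutant and 587 and 186 in the double mutant. It rose in the Dis3L2 mutant (adjusted p = 0.000445) and in the double mutant (adjusted p = 0.00407) and did not pass in the Tailor mutant (adjusted p = 0.233).

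SnoRNAs hosted by ribosomal protein genes did not differ in median from the others in the double mutant. The 47 in 18 ribosomal protein hosts had a median of -1.77 and the 83 in 39 other hosts -1.77, while the host genes had medians of -0.86 and -0.25.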
